A study of Mus musculus with 12 samples.

How the data were processed

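Poly(A) RNA from whole mouse retina was sequenced in 12 libraries, 3 in each of 4 groups formed by genotype (Pilrb1/2 wild type or knockout) and age (P28 or 12 months). Per the labels' protocols, RNA was taken with RNeasy columns, stranded mRNA libraries were made and 125-base paired reads were sequenced on an Illumina NextSeq. The series text says that Pilra and Pilrb1/2 were deleted by CRISPR in C57BL/6J zygotes, while the sample labels name Pilrb1/2 alone. Per the submitters' processing notes, reads were quantified with kallisto 0.45.0 against Ensembl 102, summarised to genes with tximport 1.30.0 and normalized with edgeR 4.0.3. Those notes name the human reference GRCh38.p7, but the deposited identifiers are mouse, and 51903 of 53028 genes were found in the GRCm38 annotation, 51760 with the same chromosome and at least 1 equal end.

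The gene values are a signal deposited by the authors as CPM per effective library, that is, divided by a TMM factor and not logged, so that the columns sum to 0.93 to 1.1 times what plain CPM would. The transcript values are RPKM as deposited by the authors, reads per kilobase of annotated length on the same kind of effective library by a check of their low values, and how they were made is not stated. Neither table holds counts, so count models were not used. The depth of each library was read back from the smallest step between its values, and the floor is 3 reads. From 9.11 to 23.4% of the low gene values were whole numbers of reads to within 0.01 reads. Fold changes are on the log2(CPM + 1) scale and understate changes of genes near a CPM of 1.

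Genes with a CPM of at least 1 in at least 3 of the 12 libraries were tested on log2(CPM + 1) with limma 3.58.1 in R 4.3.3. The model held 4 group means, eBayes ran with a trend, and p-values were adjusted by Benjamini-Hochberg at 0.05. Contrasts were knockout against wild type at P28, at 12 months and over both ages, the difference of the effect between ages, and 12 months against P28 in each genotype. The 3 targeted genes were compared by two-sided exact permutation of the mean CPM. Gene lists of retinal cell types, of other tissues that can enter a dissection and of pathways had at least 5 tested members. Tests were camera at a preset correlation of 0.01, on which list calls rest, or one estimated from the data, and fry. With the estimate 0 lists passed and with fry 6, 17, 12, 3, 5 and 13, in the order of the contrasts. Adjusted p-values over the list alone correct for its members only.

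Genes were named by a rule. Named are Pilra, Pilrb1 and Pilrb2, the 13 largest rises and 12 largest falls among genes that passed, whose libraries did not overlap between the groups and whose symbol is not a predicted or clone name, up to 4 members of a list by smallest p, up to 10 genes of the difference between ages, and genes within 1 Mb of the targeted genes that passed. Members needed to make a count clear were added. The lists, the groups, the tests, the naming rule and a set of alternative settings were chosen before the data were examined. Those settings were pseudocounts of 0.1 and 5, 2 other expression filters, quantile normalization, median-of-ratios rescaling, recomputed TMM, summed transcript RPKM, array weights, robust eBayes, a fit of only the groups compared, a replicate block, a sex term, an adjusted p of 0.10 and leaving out each library.

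Settings chosen after seeing the data were removal of a smooth GC trend, or a GC and length trend, from each library (splines of 5 degrees of freedom; 98.7% of tested genes have both), the latter with a sex term, male libraries only, and leaving out both knockout libraries numbered 2. Sex was read from Xist, at over 100 CPM in a female library, and from Y-linked genes. The steps were tested on simulated data. Noise was drawn independently for each gene and library, so the limma and camera results below do not cover correlated genes. limma recovered 24.2%, 75.5% and 98.8% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.35% false calls. Trend removal took unchanged genes called from 23.4% to 0.0485% and left 81.9% of changed ones called. The trend added there was linear in the same GC values that the removal uses. camera found the moved list in 5 of 5 runs and called 0 of 170 other list tests, and TMM rescaling erred by at most 0.26%. Within-gene GC ratios of 0, 0.5 and 1 came back as 0.00408, 0.537 and 1.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The raw reads and all other measurements of the study were not analysed here.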

Results

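Retinal poly(A) RNA was profiled in 12 mouse libraries that fell into 4 groups of 3, in 2 genotypes and at 2 ages. These were wild-type and Pilrb1/2 knockout retinas taken 28 days after birth (P28) and at 12 months of age. The depth read back from the smallest step of each library was 19.4 to 25 M reads in P28 wild type, 14.7 to 22 M reads in P28 knockout, 22.4 to 25.9 M reads in 12-month wild type and 17.1 to 21.1 M reads in 12-month knockout. At these depths a count of 3 reads corresponded to 0.111 to 0.192 CPM, the unit of the deposited gene values, a floor that covers counting error only. Between 15349 and 15857 genes reached a CPM of 1 or more in a library, and 16486 genes were tested. The labels do not say whether the 3 libraries of a group came from separate animals, so every p-value measures the spread between these libraries only. Xist, the RNA that silences the inactive X chromosome, exceeded 100 CPM in 2 of the 3 12-month wild-type libraries and in 2 of the 3 P28 knockout libraries. It was at 16.3 CPM or lower in the other 8, all of which held Y-linked transcripts. The sexes, which the labels do not give, therefore differed between the genotypes at each age, while over both ages each genotype held 4 male and 2 female libraries.

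To examine the deleted locus, the 3 targeted genes were read first. Pilrb1 (ENSMUSG00000066684, GRCm38 chromosome 5, 137852147 to 137858106) and Pilrb2 (ENSMUSG00000066682, chromosome 5, 137865827 to 137871815) encode paired activating immunoglobulin-like receptors. Pilrb1 was at 0.052 CPM in 12-month knockout library 2 and Pilrb2 at 0.0436 CPM in 12-month wild-type library 1, about 1 read each. Each was listed at 0 in the other 11, so they cannot show which libraries carry the deletion. Pilra (ENSMUSG00000046245, chromosome 5, 137821952 to 137836281), the inhibitory receptor gene beside them, was at 0.133, 0.167 and 0.17 CPM in P28 wild type and at 0.441, 1.16 and 0.819 CPM in P28 knockout. At 12 months it was at 0.159, 0.221 and 0.268 CPM in wild type and 0.0556, 0.309 and 0.293 CPM in knockout. The P28 means were 0.157 ± 0.0208 and 0.805 ± 0.358 CPM (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest this design allows). The 12-month means were 0.216 ± 0.0549 and 0.219 ± 0.142 CPM (exact permutation p = 1). With genotype permuted within age the exact p over both ages was 0.05, or 0.04 with summed transcript RPKM. On CPM it ran from 0.01 without 12-month knockout library 1 to 0.135 without P28 wild-type library 1. Pilra, also deleted per the series text, was above 0 in all 6 knockout libraries. At P28 it was above every wild-type library, where it lay just above 3 reads. Pilra-203, a retained-intron form, was at 0, 0.274 and 0.148 RPKM in P28 knockout and coding Pilra-201 at 0.21, 0.185 and 0.161. These values show no lower signal at P28, but not whether exons were lost. All 3 genes lay below the expression filter of the gene-wise tests.

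**Figure D1:**
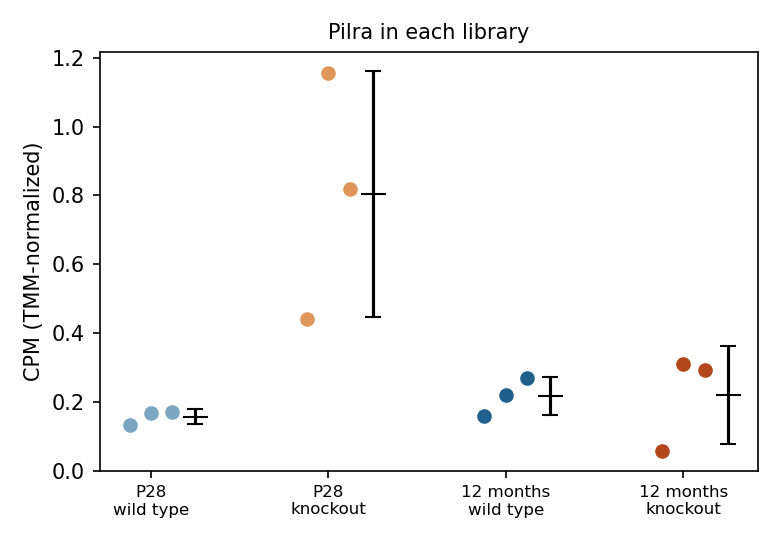
Pilra in CPM for each of the 12 libraries, by group, with the group mean and SD (n = 3). The 3 P28 knockout libraries lay between 0.441 and 1.16 CPM and the other 9 at 0.309 CPM or lower.

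To identify genes that differed between genotypes in the young adult retina, knockout was compared with wild type at P28 (n = 3 libraries each; ± is the limma standard error). Egr1 (log2 fold change -1.63 ± 0.24, adjusted p = 0.0151) and Fos (log2 fold change -1.095 ± 0.13, adjusted p = 0.00653), which encode transcription factors induced by activity, were lower in knockout. The adult globin genes Hbb-bt (log2 fold change -1.29 ± 0.20, adjusted p = 0.0167), Hba-a2 (-1.28, adjusted p = 0.0473) and Hba-a1 (-1.25, adjusted p = 0.0269), which share reads with near-identical copies, fell as well. Ifit3, induced by interferon, fell (log2 fold change -1.18 ± 0.20, adjusted p = 0.0223). So did Pds5a, a regulator of cohesin (log2 fold change -1.01 ± 0.09, adjusted p = 0.00177). Among the largest rises were Anxa3, a calcium-dependent phospholipid-binding annexin (log2 fold change 1.02 ± 0.19, adjusted p = 0.0306), and Lrp2, the endocytic receptor megalin (log2 fold change 0.91 ± 0.12, adjusted p = 0.0128). Abca1, which exports cholesterol from cells, rose as well (log2 fold change 0.78 ± 0.17, adjusted p = 0.0433).

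Further rises were in Prex1, an exchange factor for Rac GTPases (1.01), Mark1, a microtubule-affinity kinase (0.90), the kinesin Kif13b (0.86), the transcription factor Zbtb20 (0.78), Raph1 (0.77), N4bp2 (0.83), Fam228a (0.81) and Fbf1 (0.76). Their adjusted p ran from 0.0128 to 0.0413. The pseudogene Apoo-ps (1.86, adjusted p = 0.0334) and the olfactory receptor gene Olfr1459 (0.99, adjusted p = 0.0223) also rose, both in families whose members share reads. Further falls were in the ribosomal protein gene Rpl11 (-1.11), Bola2 (-1.25), Fam220a (-1.07), Alox5ap, needed for leukotriene synthesis (-1.06), and Timm13, a mitochondrial import chaperone (-1.004). Adjusted p for these ran from 0.03 to 0.0413.

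Of 35 gene lists fixed before the data were examined, 10 passed at P28 and none of them did with an estimated correlation, where the smallest adjusted p was 0.14. Of the 10, 8 passed in the same direction with GC and length trends removed. Cholesterol synthesis and uptake fell (median log2 fold change -0.35; camera adjusted p = 1.62e-09, and adjusted p = 0.14 with an estimated correlation). Of its 20 members 3 fell over all genes and 14 adjusted over the list alone. Among them were Insig1 (-0.63, adjusted p = 0.0291) and Msmo1, a sterol oxidase (-0.62, adjusted p = 0.0134). The respiratory chain fell as a group (median -0.34; camera adjusted p = 5.96e-10, and adjusted p = 0.263 with an estimated correlation), with 0 of 32 members past the limma threshold over all genes and 15 lower adjusted over the list alone. Its values included mt-Cytb at -0.67, adjusted p = 0.0786, and Cox6c at -0.41, adjusted p = 0.0825. Transcripts of the mitochondrial genome held 4.56 to 7.08% of the signal in P28 knockout and 7.36 to 9.31% in P28 wild type. The interferon response and antigen presentation list fell (median -0.41; camera adjusted p = 5.31e-05, and adjusted p = 0.306 with an estimated correlation), with Ifit3 and Ifit1 (-0.98, adjusted p = 0.0225) past the threshold over all genes and 6 members adjusted over the list alone. Immediate early genes fell (median -0.29; camera adjusted p = 0.00134, and adjusted p = 0.14 with an estimated correlation), with Fos, Egr1 and Dusp1 (-0.84, adjusted p = 0.0167) past it over all genes and 5 adjusted over the list alone.

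The erythrocyte list fell (camera adjusted p = 3.25e-05, and adjusted p = 0.263 with an estimated correlation), with 3 of 5 members lower over all genes and 5 adjusted over the list alone. Its summed signal was 12.6 to 23.6 CPM in P28 knockout and 32.5 to 49.6 CPM in P28 wild type. The oxidative stress list fell (camera adjusted p = 0.00134, and adjusted p = 0.306 with an estimated correlation; 0 of 19 members over all genes, 6 lower adjusted over the list alone). Mt1 was at -0.65, adjusted p = 0.07. The rod phototransduction list fell (median -0.21; camera adjusted p = 0.00177, and adjusted p = 0.577 with an estimated correlation). None of its 28 members passed over all genes or adjusted over the list alone. The cone list did not pass (camera adjusted p = 0.198, and adjusted p = 0.685 with an estimated correlation). Its members Gnat2, the cone transducin subunit (-0.41, adjusted p = 0.0291), Pde6h, a cone phosphodiesterase subunit (-0.94, adjusted p = 0.0388), and Opn1sw, the short-wavelength opsin (-0.52, adjusted p = 0.0457), fell. These were 3 of 15 over all genes, and 3 fell and 2 rose adjusted over the list alone.

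Calcium handling rose (median 0.19; camera adjusted p = 0.00306, and adjusted p = 0.306 with an estimated correlation), with 0 of 24 members over all genes and 6 adjusted over the list alone. It was at adjusted p = 0.288 once GC and length trends were removed. Microglia and macrophage markers rose (camera adjusted p = 0.0357, and adjusted p = 0.536 with an estimated correlation), with Itgam, the integrin CD11b (0.68, adjusted p = 0.0397), past the threshold over all genes and 4 of 18 adjusted over the list alone. That call was lost without P28 wild-type library 2 or P28 knockout library 1 or 2, at an adjusted p of up to 0.27. Glycolysis fell (camera adjusted p = 0.0287, and adjusted p = 0.748 with an estimated correlation) with Hk2, a hexokinase, lower (-0.83, adjusted p = 0.0242) and Pdk1, which inhibits pyruvate dehydrogenase, higher (0.47, adjusted p = 0.0373). Over all genes these were 1 each and adjusted over the list alone 4 fell and 1 rose, and the call was lost without P28 wild-type library 1 or P28 knockout library 3 (up to 0.415). It was lost as well with GC and length trends removed (median -0.18 before and -0.08 after, adjusted p = 0.207). Outside the called lists, Xbp1 (0.60, adjusted p = 0.0242) and Hspa5 (0.75, adjusted p = 0.0433), both of the unfolded protein response, rose. So did Nes, raised in reactive glia (0.76, adjusted p = 0.0377), and Rpgr, whose product works in the connecting cilium (0.47, adjusted p = 0.0362). Of the age-related macular degeneration orthologs, Kmt2e (0.64, adjusted p = 0.039), Abca1 and Srpk2 (0.37, adjusted p = 0.049) rose over all genes, and 0 members rose with GC and length trends removed. Adjusted over the list alone 3 rose and 1 fell, and the list itself did not pass (camera adjusted p = 0.0642, and adjusted p = 0.263 with an estimated correlation). None of the 8 tested PILR partners and adaptors passed limma over all genes, nor did any of the 54 tested genes within 1 Mb of the locus.

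In all 246 genes passed limma at P28, 165 higher and 81 lower in knockout, and 3533 had an unadjusted p under 0.05. The genotypes did not overlap for each of these 246 genes and for 23.8% of all tested genes, where chance alone gives 10%. More genes rose than fell after quantile normalization (176 and 141), median-of-ratios rescaling (196 and 69) and recomputed TMM (171 and 69). More fell than rose with summed transcript RPKM (210 and 119), the GC trend removed (334 and 316), GC and length trends removed (140 and 109) and male libraries only (18 and 5). The count was 7, 81 and 3 without P28 wild-type libraries 1, 2 and 3, and 1404 and 6 without P28 knockout libraries 2 and 3. Of the 25 largest rises and falls 1 passed in every leave-one-out fit. With GC and length trends removed 115 of the 246 passed in the same direction. So did 20 of the 25, but not Abca1, Zbtb20, Hba-a2, Hba-a1 or Timm13. The effect followed length (Spearman 0.43) more than GC (-0.34). The count was 1 with a sex term, Pds5a, and 0 in limma on P28 libraries only (2615 at unadjusted p under 0.05). P28 knockout library 2 held 5951 CPM of lens transcripts, followed by P28 wild-type library 3 with 2297 CPM.

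To identify genes that differed between genotypes in the aged retina, knockout was compared with wild type at 12 months (n = 3 each). Rab3a, a synaptic vesicle GTPase, was lower in knockout (log2 fold change -2.49 ± 0.58, adjusted p = 0.00672). So were Ptov1 (log2 fold change -2.07 ± 0.29, adjusted p = 0.00244) and Ptgds, the lipocalin-type prostaglandin D synthase (log2 fold change -2.01 ± 0.53, adjusted p = 0.0114). Sema3d, a secreted axon guidance factor (log2 fold change 1.52 ± 0.28, adjusted p = 0.00332), and Fgfbp3, which binds fibroblast growth factors (log2 fold change 1.297 ± 0.22, adjusted p = 0.00283), were higher. The mitochondrial gene mt-Nd6 was too (log2 fold change 1.35 ± 0.21, adjusted p = 0.00256). The largest rises of all, in the Y-linked genes Eif2s3y (4.92), Ddx3y (4.61) and Uty (2.73), followed the 2 female libraries in 12-month wild type and 0 in 12-month knockout.

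Further rises were in Pzp, a protease inhibitor of the alpha-2-macroglobulin family (1.37), the serpin Serpina3k (1.35), Csta1 (1.28), the fibrinogen chain gene Fga (1.23), the nuclear RNA Malat1 (1.26), Gt(ROSA)26Sor and Olfr1271 (1.25), the last in a family with shared reads (adjusted p 0.00325 to 0.0462). Further falls were in the ribosomal protein gene Rps15 (-1.97), Bola2 (-1.94), Ppp1r37 (-2.03), the retinol dehydrogenase relative Rdh16f1 (-1.93), Ndufb7 of respiratory complex I (-1.91), Atp5d of the ATP synthase (-1.91) and the pseudogene Tpt1-ps3 (-2.16). Their adjusted p ran from 0.00237 to 0.0121. The pseudogene Rpl15-ps3 (adjusted p = 0.00298) was at 4.88 ± 1.42 CPM in wild type and listed at 0 in all 3 knockout libraries. Pseudogenes share reads with their parent genes. Transcripts of the mitochondrial genome held 9.94 to 12.6% of the signal in 12-month knockout and 7.36 to 8.29% in 12-month wild type.

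Of the 35 lists 6 passed at 12 months, all lower in knockout, and none did with an estimated correlation. Glycolysis and the cone list, 2 of the 6, passed with GC and length trends removed. Glycolysis fell most clearly (median -0.70; camera adjusted p = 0.000108, and adjusted p = 0.689 with an estimated correlation), with 18 of 21 members lower and 1 higher over all genes and 18 and 2 adjusted over the list alone. Among them were Aldoa, aldolase A (log2 fold change -1.65 ± 0.29, adjusted p = 0.00293), and the phosphofructokinase gene Pfkl (log2 fold change -1.41 ± 0.25, adjusted p = 0.00298). With GC and length trends removed its median was -0.35 (camera adjusted p = 8.92e-05) and 9 members were lower. The cone list fell (median -0.46; camera adjusted p = 0.035, and adjusted p = 0.689 with an estimated correlation), with 8 of 15 members lower and 1 higher over all genes and 9 and 1 adjusted over the list alone. Gnb3 (-1.46, adjusted p = 0.00248), Pde6h (-1.23, adjusted p = 0.00262) and Gngt2 (-0.91, adjusted p = 0.00293), all of the cone cascade, were among them. With the trends removed its median was -0.22 (adjusted p = 8.92e-05) and 6 members fell. Its call was lost without 12-month wild-type library 1 or 12-month knockout library 3, at an adjusted p of up to 0.0968. The rod list did not pass (camera adjusted p = 0.306, and adjusted p = 0.89 with an estimated correlation). Of its 28 members 11 fell, including Pde6g, a rod phosphodiesterase subunit (-1.38, adjusted p = 0.00316), Cngb1, of the rod cyclic-nucleotide channel (-0.79, adjusted p = 0.00352), and Reep6 (-1.01, adjusted p = 0.00364). Another 3 rose, and these counts were the same adjusted over the list alone. With the trends removed 3 fell and 1 rose (median -0.11 before and -0.06 after, adjusted p = 0.426).

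Endothelial and pericyte markers fell (median -0.45; camera adjusted p = 0.0314, and adjusted p = 0.689 with an estimated correlation), 6 of 15 over all genes and adjusted over the list alone. Cldn5, of the endothelial tight junction, was at -0.76, adjusted p = 0.00512. Once GC and length trends were removed the list was at adjusted p = 0.407 and 0 members passed. It was lost without 12-month wild-type library 1 or knockout library 3 (up to 0.064). The interferon list fell (camera adjusted p = 0.0314, and adjusted p = 0.691 with an estimated correlation), with 6 of 20 members lower over all genes and 4 adjusted over the list alone, led by H2-D1, a classical MHC class I gene (-0.92, adjusted p = 0.00263). Its call was lost without 12-month wild-type library 2 or 12-month knockout library 1 or 3 (up to 0.098), and with GC and length trends removed (median -0.34 before and -0.20 after, adjusted p = 0.0541; 2 members lower). All 5 erythrocyte genes fell over all genes and adjusted over the list alone (camera adjusted p = 0.0264, and adjusted p = 0.689 with an estimated correlation). Hba-a2 was at -1.58, adjusted p = 0.00308, and the call was lost without 12-month knockout library 3 (0.064) and with the trends removed (median -1.01 before and -0.76 after, adjusted p = 0.0686; 2 members lower). Their summed signal was 4.33 to 9.94 CPM in knockout and 19.2 to 34.1 CPM in wild type. Microglia and macrophage markers did not pass as a list (camera adjusted p = 0.0541, and adjusted p = 0.689 with an estimated correlation). Over all genes and adjusted over the list alone 8 of 18 fell, including the complement genes C1qb (-1.11, adjusted p = 0.00283), C1qc (-0.81, adjusted p = 0.00406) and C1qa (-0.79, adjusted p = 0.00439). After trend removal 1 of the 18 fell (median -0.33 before and -0.12 after, adjusted p = 0.292).

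The targeted locus neighbours fell (median -0.45; camera adjusted p = 0.00698, and adjusted p = 0.689 with an estimated correlation), 16 of 34 lower and 1 higher over all genes and 17 and 1 adjusted over the list alone. With GC and length trends removed their median was 0.00 and the test turned direction (adjusted p = 0.976). Of 54 tested genes within 1 Mb, 25 fell and 3 rose. Gnb2, a G protein subunit (log2 fold change -1.74 ± 0.32, adjusted p = 0.00316), fell most. The others were Col26a1, Plod3, Ap1s1, Ift22, Fis1, Cops6, Ache, Trip6, Fam20c, Actl6b, Gigyf1, Pop7, Gm20605, Tsc22d4, Mepce, Map11, Zscan21, Mospd3, Srrt, Vgf, Nyap1, Lamtor4, Znhit1 and Sap25. The 3 that rose were Zkscan1, Zfp157 and Zfp68. Once GC and length trends were removed 2 of the 54 fell, Gnb2 (-0.98, adjusted p = 0.0305) and Gm20605 (-0.73, adjusted p = 0.0493), and 1 rose. Of the PILR partners and adaptors, Npdc1 (-0.87, adjusted p = 0.00644), Tyrobp, the DAP12 adaptor (-0.76, adjusted p = 0.0111), and Ptpn11 (-0.28, adjusted p = 0.0278) fell. These were 3 of 8 over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0552, and adjusted p = 0.689 with an estimated correlation for the list). After trend removal 0 of the 8 fell (median -0.42 before and -0.09 after).

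In all 6536 genes passed limma at 12 months, 2655 higher and 3881 lower in knockout, with 8196 at unadjusted p under 0.05. The libraries of the 2 genotypes did not overlap for 6434 of them and for 59.1% of all tested genes, where chance alone gives 10%. The change followed the GC content of the transcripts, with a median log2 fold change from 0.38 in the 20% of genes lowest in GC to -0.66 in the 20% highest in GC (Spearman correlation -0.77 across genes, which are not independent replicates). Between transcripts of the same gene, the slope of log2 signal, relative to the mean of all libraries, was 0.193 to 0.414 per 10 points of GC in wild-type and -0.716 to -0.325 in knockout libraries. With GC and length trends removed 1196 genes passed, 622 up and 574 down. Of these 829 were among the 6536 with the same direction. With a sex term as well 61 genes passed. Of the 25 largest rises and falls 16 of 24 with a GC value passed with the trends removed, and Eif2s3y, Ddx3y, Uty, Pzp, Serpina3k, Malat1, Olfr1271 and Ptgds did not. Up and down calls numbered 2963 and 3017 after quantile normalization, 3230 and 3561 after median-of-ratios rescaling, 3222 and 3555 with recomputed TMM and 2740 and 3773 with summed transcript RPKM. The count on the deposited values was 3933 without 12-month wild-type library 1, 4202 without wild-type library 3 and 3552 without knockout library 2.

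**Figure D2:**
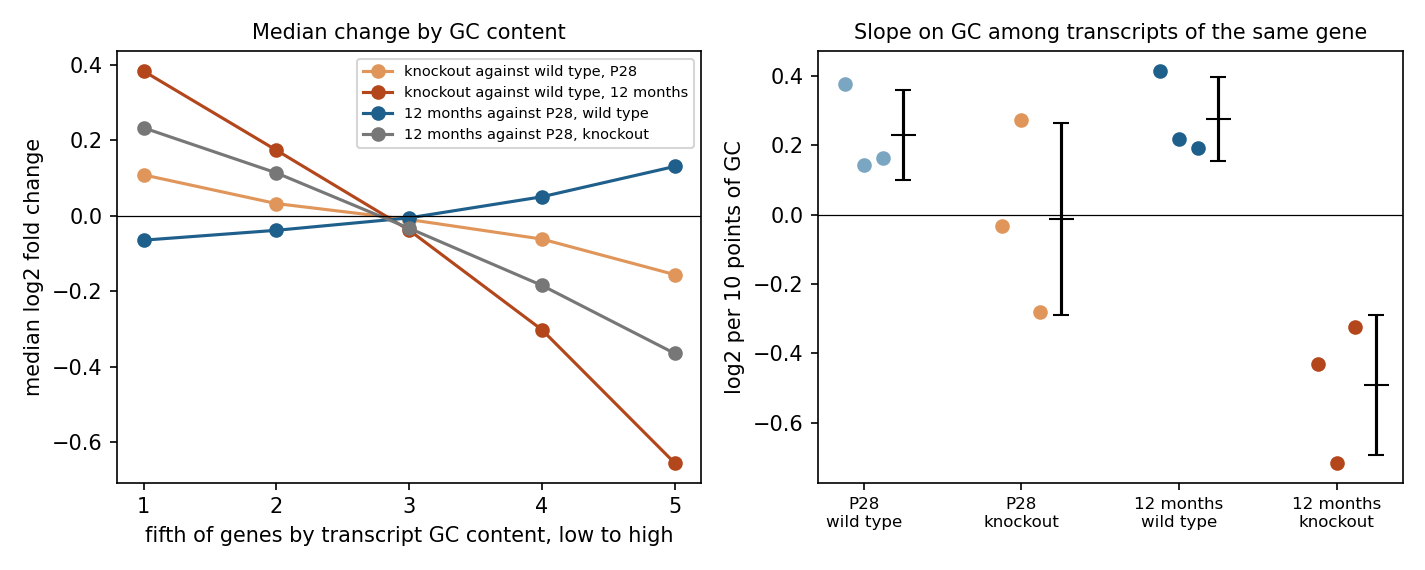
Left, median log2 fold change of the genes in each 20% step of GC content for 4 comparisons; right, slope of log2 signal on GC between transcripts of the same gene for each library, with the group mean and SD (n = 3). At 12 months the medians ran from 0.38 to -0.66 and at P28 from 0.11 to -0.16, and all 3 12-month knockout slopes lay below all 3 of 12-month wild type.

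To estimate the knockout effect over both ages, the effects at P28 and 12 months were averaged, in which each genotype had 4 male and 2 female libraries. A gene can pass here through 1 age alone. Notch1, a receptor of cell-fate signalling, rose (log2 fold change 0.89 ± 0.25, adjusted p = 0.0179), as did Glcci1, a glucocorticoid-induced gene (log2 fold change 0.75 ± 0.09, adjusted p = 0.000964). The ubiquitin gene Ubb (log2 fold change -1.29 ± 0.21, adjusted p = 0.00246) and Bola2 (log2 fold change -1.60 ± 0.17, adjusted p = 0.000896) fell. Further falls were in the ribosomal protein genes Rpl35 (-1.56), Rps15 (-1.46) and Rpl8 (-1.31), Atp5g1 of the ATP synthase (-1.32) and Ndufa11 of complex I (-1.27). Ptov1 (-1.405), Zfp385a (-1.28), Hba-a2 (-1.43) and Tpt1-ps3 (-1.64) fell too. Adjusted p for these ran from 0.00181 to 0.00542. Further rises were in Brwd3 (0.75), Scai (0.74), Tc2n (0.79), Zfp968 (0.72) and Mir1898 (0.83). The chemoreceptor genes Olfr1459 (0.82), Olfr1100 (0.73), Olfr889 (0.73), Vmn2r53 (0.82), Vmn1r229 (0.81) and Vmn2r17 (0.74), from large families with shared reads, rose too (adjusted p 0.000896 to 0.008 for these 11). Each of the 25 genes with the largest rises and falls passed whichever single library was left out, and 22 passed with GC and length trends removed, the others being Tc2n, Olfr1100 and Rpl35.

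Over both ages 10 of the 35 lists passed, all lower in knockout, and none did with an estimated correlation (smallest adjusted p = 0.611). Trend removal for GC and length left 8 of the 10 past the threshold in the same direction. Cholesterol synthesis and uptake fell (median -0.29; camera adjusted p = 0.000236, and adjusted p = 0.611 with an estimated correlation), 11 of 20 members over all genes and 14 adjusted over the list alone. The mevalonate-pathway gene Mvd was at log2 fold change -0.80 ± 0.14, adjusted p = 0.00281. Once GC and length trends were removed 12 members fell. Glycolysis fell (median -0.46; camera adjusted p = 0.000117, and adjusted p = 0.733 with an estimated correlation), with 15 of 21 members lower and 1 higher over all genes and 17 and 1 adjusted over the list alone. Gapdh was at -0.98, adjusted p = 0.00283, and Tpi1 at -0.90, adjusted p = 0.00335. The interferon list fell (median -0.36; camera adjusted p = 0.000472, and adjusted p = 0.705 with an estimated correlation), 11 of 20 over all genes and 12 adjusted over the list alone. H2-D1 was at -0.73, adjusted p = 0.00181, and Ifit3 at -0.83, adjusted p = 0.00261. The erythrocyte list fell, 5 of 5 over all genes and adjusted over the list alone (camera adjusted p = 0.000755, and adjusted p = 0.642 with an estimated correlation). Immediate early genes fell (camera adjusted p = 0.0194, and adjusted p = 0.611 with an estimated correlation), 6 of 14 over all genes and 7 adjusted over the list alone. Egr1 was at -1.08, adjusted p = 0.00209. The list median went from -0.36 to 0.01 with GC and length trends removed (adjusted p = 0.374).

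The rod list fell (median -0.14; camera adjusted p = 0.0414, and adjusted p = 0.903 with an estimated correlation), with 13 of 28 members lower and 2 higher over all genes and 14 and 2 adjusted over the list alone. These included Gnat1, rod transducin (log2 fold change -0.81 ± 0.16, adjusted p = 0.00352), Pde6g (-1.06, adjusted p = 0.00266), and Guca1b, a guanylate cyclase activator (-0.79, adjusted p = 0.00297). Its call was lost in 7 of the 12 leave-one-out fits, those without 12-month wild-type library 1 or 2, 12-month knockout library 2 or 3, P28 wild-type library 1 or P28 knockout library 1 or 2 (up to 0.0931). With GC and length trends removed its median was -0.13 (adjusted p = 0.00186) and 8 members fell. The cone list fell (median -0.30; camera adjusted p = 0.0393, and adjusted p = 0.733 with an estimated correlation), with 7 of 15 lower and 1 higher over all genes and 8 and 2 adjusted over the list alone. They were led by Pde6h (-1.08, adjusted p = 0.00127) and Opn1sw (-0.55, adjusted p = 0.00187). Its call was lost without 12-month knockout library 3, P28 wild-type library 1 or P28 knockout library 1 or 2 (up to 0.072). The respiratory chain fell (camera adjusted p = 0.0395, and adjusted p = 0.903 with an estimated correlation), 12 of 32 over all genes and adjusted over the list alone. Ndufa2 was at -1.01, adjusted p = 0.00212, and the list call was lost without 12-month wild-type library 2, 12-month knockout library 3, P28 wild-type library 1 or 3 or P28 knockout library 2 (up to 0.319). The oxidative stress list fell (camera adjusted p = 0.0257, and adjusted p = 0.733 with an estimated correlation), 10 of 19 over all genes and adjusted over the list alone. The metallothionein Mt1 was at -0.98, adjusted p = 0.0011, and the list call was lost without P28 wild-type library 3 (0.0504). Photoreceptor outer segment and cilium genes went both ways, 6 up and 6 down over all genes and adjusted over the list alone (camera adjusted p = 0.737, and adjusted p = 0.989 with an estimated correlation). Rpgr (0.58, adjusted p = 0.000896) and Cep290 (0.44, adjusted p = 0.00266) were higher and Prph2, a disc-rim protein gene (-0.52, adjusted p = 0.0027), lower. With the trends removed 6 glycolysis, 7 interferon, 3 erythrocyte, 4 immediate early, 5 cone, 4 respiratory chain and 4 oxidative stress genes fell, and of the outer segment genes 4 rose and 3 fell.

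The locus neighbours fell on the deposited values (camera adjusted p = 0.0048, and adjusted p = 0.733 with an estimated correlation; 13 of 34 over all genes, 14 adjusted over the list alone) but were at adjusted p = 0.93 with GC and length trends removed. Within 1 Mb 23 of 54 genes fell and Zfp157 rose (0.29, adjusted p = 0.00649). Of those 23, Ufsp1 and 6330418K02Rik had not passed at 12 months, and Pop7, an RNase P subunit (-0.76, adjusted p = 0.00294), and Mospd3 (-0.62, adjusted p = 0.00393) were among the rest. With the trends removed Ift22 (-0.36, adjusted p = 0.0442) and Fis1 (-0.29, adjusted p = 0.0484) fell and 1 gene rose. In all 5796 genes passed limma over both ages, 2361 higher and 3435 lower, with 7631 at unadjusted p under 0.05. Up and down calls were 2450 and 2694 after quantile normalization and 2834 and 3079 after median-of-ratios rescaling, and turned to 292 and 121 with male libraries only. Once GC and length trends were removed 1704 passed, 710 higher and 994 lower. Of these 1194 were called before in the same direction, and 1476 passed with a sex term as well.

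**Figure D3:**
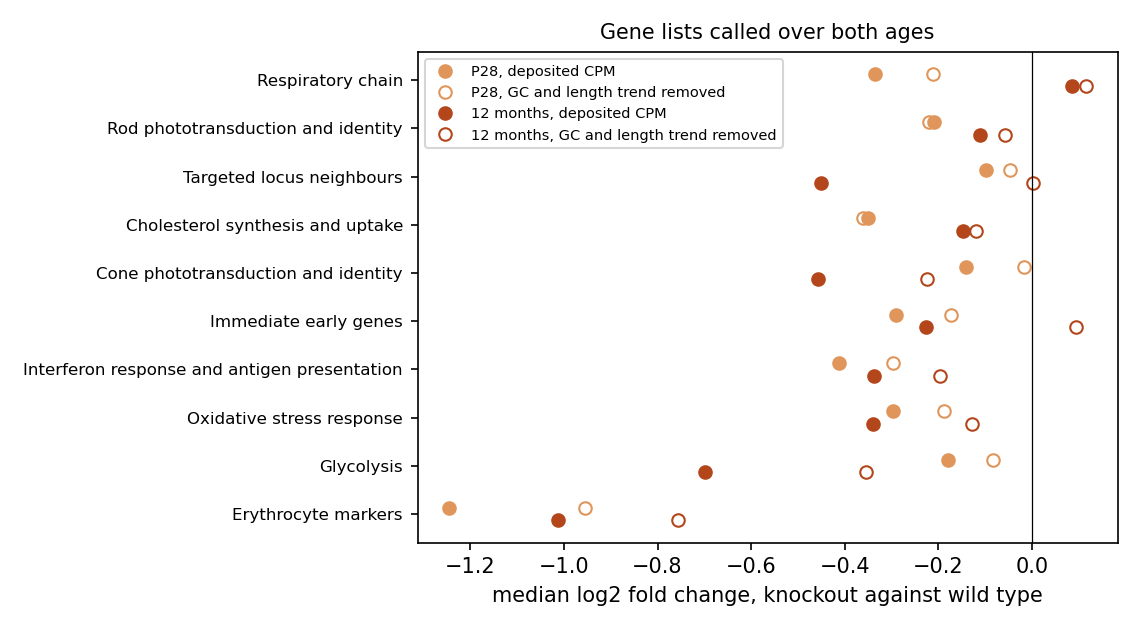
Median log2 fold change, knockout against wild type, at P28 and at 12 months for the 10 lists that passed over both ages, on the deposited CPM (filled) and with GC and length trends removed (open). The median of the glycolysis list at 12 months went from -0.70 to -0.35 and that of the locus neighbours from -0.45 to 0.00 when the trends were removed.

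To test whether the knockout effect differed between ages, the effect at P28 was subtracted from that at 12 months. Pds5a had the firmest difference, 1.503 ± 0.13 (adjusted p = 0.000958), being -1.01 at P28 and 0.49 at 12 months. The RNA-binding protein gene Hnrnpa1 (difference 0.78 ± 0.11, adjusted p = 0.0244), the chromatin protein gene Hmgb2 (1.02, adjusted p = 0.0329), Hnrnpdl (0.79, adjusted p = 0.041) and the kinase gene Stk17b (0.96, adjusted p = 0.0344) had estimates below 0 at P28 and above 0 at 12 months. So did mt-Nd3 of complex I (1.80, adjusted p = 0.0244), beside the mitochondrial shares above. Map4k4, a kinase (-0.95, adjusted p = 0.0372), Selenbp1 (-1.497, adjusted p = 0.0372) and AC149090.1 (-1.81, adjusted p = 0.0244) had the reverse. Acte1 (adjusted p = 0.0329) was at 1.52 ± 0.414 CPM in 12-month wild type and listed at 0 in the other 9 libraries.

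Of the 35 lists 10 differed between ages, none with an estimated correlation. Once the GC and length trends were removed 6 of the 10 differed in the same direction. The endothelial (adjusted p = 0.0954), calcium handling (0.0764), extracellular matrix (0.239) and locus neighbour (0.814) lists did not. The respiratory chain difference was positive (median 0.32; camera adjusted p = 0.000185, and adjusted p = 0.572 with an estimated correlation). Over all genes it held 1 of 32, mt-Nd2 (1.45, adjusted p = 0.0478), and 16 adjusted over the list alone. That of cholesterol synthesis was positive (camera adjusted p = 0.0451, and adjusted p = 0.572 with an estimated correlation; 0 of 20 over all genes, 6 positive and 1 negative adjusted over the list alone). It was lost in 8 of 12 leave-one-out fits, those without 12-month wild-type library 2 or 3, 12-month knockout library 1 or 3, P28 wild-type library 1 or 2 or P28 knockout library 1 or 3 (up to 0.246). The microglia difference was negative (median -0.61; camera adjusted p = 0.000285, and adjusted p = 0.572 with an estimated correlation), 1 of 18 over all genes, the fractalkine receptor gene Cx3cr1 (-1.05, adjusted p = 0.0478), and 8 adjusted over the list alone. The glycolysis (camera adjusted p = 0.00303, and adjusted p = 0.572 with an estimated correlation; 1 of 21, Hk2 at 1.24, adjusted p = 0.041, and 2 positive and 10 negative adjusted over the list alone) and endothelial (camera adjusted p = 0.00695, and adjusted p = 0.572 with an estimated correlation; 0 of 15 over all genes and 3 adjusted over the list alone) lists were negative. So, with the members counted in the same order, were calcium handling (camera adjusted p = 0.00695, and adjusted p = 0.572 with an estimated correlation; 0 of 24 and 6) and unfolded protein response (camera adjusted p = 0.00831, and adjusted p = 0.572 with an estimated correlation; 0 of 20, and 1 positive and 6 negative). Gliosis was negative (camera adjusted p = 0.0147, and adjusted p = 0.572 with an estimated correlation; 0 of 19 and 9), and lost without P28 wild-type library 2 (0.0923). Extracellular matrix was negative (camera adjusted p = 0.0343, and adjusted p = 0.572 with an estimated correlation; 0 of 29 and 0), and lost without 12-month wild-type library 1, 12-month knockout library 1, P28 wild-type library 2 or P28 knockout library 1 (up to 0.233). The locus neighbours were negative (camera adjusted p = 0.0315, and adjusted p = 0.572 with an estimated correlation; 0 of 34 and 1), and lost without P28 wild-type library 2 or 3 or P28 knockout library 1 or 2 (up to 0.0752). They turned direction with GC and length trends removed (median 0.02).

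In all 29 genes passed limma for the difference, 13 positive and 16 negative, with 4397 at unadjusted p under 0.05. The split was 14 and 8 after quantile normalization and 22 and 17 after median-of-ratios rescaling. With GC and length trends removed 5 genes passed, all positive and 3 of them shared, namely Pds5a, Hnrnpa1 and Hk2. With a sex term limma called 0 genes, at 2962 with unadjusted p under 0.05. The count was 2 without 12-month wild-type library 1, 1 without 12-month wild-type library 2 or 3, 12-month knockout library 1 or 2, P28 wild-type library 1, 2 or 3 or P28 knockout library 1. It was 802, 235 and 2501 without 12-month knockout library 3 and P28 knockout libraries 2 and 3. Pds5a was the only one of the 10 named genes called in every leave-one-out fit. Across the 16486 genes the knockout effects at P28 and 12 months correlated at Pearson r = 0.364 with a jackknife standard error of 0.259 over libraries, and at a Spearman correlation of 0.419. Once GC and length trends were removed r was 0.179. Genes called at both ages numbered 83 in the up direction against 26.6 for independent calls, 36 in the down direction against 19.1, and 10 in opposite directions.

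To describe ageing in wild-type retina, 12 months was compared with P28 in that genotype (n = 3 each, 2 female libraries at 12 months and 0 at P28). Complement C4b rose (log2 fold change 2.78 ± 0.35, adjusted p = 0.000417), as did Lyz2, the lysozyme of macrophages (log2 fold change 2.38 ± 0.35, adjusted p = 0.00141). So did Hdc, which makes histamine (log2 fold change 3.26 ± 0.42, adjusted p = 0.000502), Glb1l3, a beta-galactosidase-like gene (log2 fold change 3.61 ± 0.13, adjusted p = 1.56e-08), and the basement membrane collagen Col4a3 (log2 fold change 3.07 ± 0.53, adjusted p = 0.00425). The lens crystallin Crygb fell (log2 fold change -4.13 ± 1.05, adjusted p = 0.0388), and lens transcripts summed to 28.8 to 2297 CPM at P28 and 25.9 to 74.2 CPM at 12 months in wild type. Further rises were in Csrp3 (3.10), the lectin receptor Ly75 (2.46), the sugar-phosphate transporter relative Slc37a2 (2.41), the secreted prokineticin Prok1 (2.23), Shisal2b (2.45), Tigd4 (2.58) and the pseudogene Smarca5-ps (2.54). Their adjusted p ran from 5.05e-07 to 0.000116. Further falls were in Rspo2, an enhancer of Wnt signalling (-2.23), the axonemal dynein genes Wdr63 (-2.45) and Dnaic2 (-1.86), Tmem26 (-2.42), Gulp1 (-1.78), Marcksl1 (-1.68) and Apobec2 (-2.10, listed under 2 identifiers with the same values). Adjusted p for these ran from 8.87e-05 to 0.0105. The near-identical homeobox genes Duxbl1 (-2.70), Duxbl2 (-2.25) and Duxbl3 (-2.76) fell with shared reads.

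In wild type 10 of the 35 lists passed with age, 10 of them in the same direction with GC and length trends removed and 0 with an estimated correlation. The interferon response and antigen presentation list rose with age in wild type (median 0.68; camera adjusted p = 3.16e-14, and adjusted p = 0.155 with an estimated correlation), 11 of 20 members over all genes and 17 adjusted over the list alone. Ifit1 was at log2 fold change 1.29 ± 0.17, adjusted p = 0.000483, Oasl2 at log2 fold change 0.98 ± 0.13, adjusted p = 0.000714, and Rsad2 at log2 fold change 1.01 ± 0.16, adjusted p = 0.00202. Microglia and macrophage markers rose (median 0.35; camera adjusted p = 2.75e-05, and adjusted p = 0.347 with an estimated correlation), 4 of 18 over all genes and 7 adjusted over the list alone. C1qb was at 0.92, adjusted p = 0.0124, and the protease gene Ctss at 0.72, adjusted p = 0.0379. Complement rose (camera adjusted p = 0.000538, and adjusted p = 0.446 with an estimated correlation), 3 of 16 over all genes and 9 adjusted over the list alone. Gliosis rose (camera adjusted p = 0.000777, and adjusted p = 0.446 with an estimated correlation), 5 of 19 over all genes and 7 adjusted over the list alone. The cytokine receptor Osmr was at 1.099, adjusted p = 0.000999, and endothelin Edn2 at 2.04, adjusted p = 0.00173. Retinal ganglion cell markers fell (median -0.34; camera adjusted p = 0.000176, and adjusted p = 0.446 with an estimated correlation), although 0 of 17 passed over all genes or adjusted over the list alone. The neurofilament gene Nefh was at -0.43, adjusted p = 0.0886. Lens markers fell (camera adjusted p = 2.75e-05, and adjusted p = 0.748 with an estimated correlation; 1 of 17 over all genes, 4 adjusted over the list alone). Amacrine markers fell (camera adjusted p = 0.0151, and adjusted p = 0.869 with an estimated correlation; 1 of 20, calretinin Calb2 at -0.46, adjusted p = 0.00866, and 5 adjusted over the list alone). The call was lost without P28 wild-type library 2 or 3 (up to 0.0873).

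Cholesterol synthesis fell (camera adjusted p = 0.0461, and adjusted p = 0.748 with an estimated correlation; 2 of 20 over all genes and 3 adjusted over the list alone). The list call was lost without 12-month wild-type library 2 or 3 or P28 wild-type library 1 (up to 0.1). The respiratory chain (camera adjusted p = 0.00858, and adjusted p = 0.869 with an estimated correlation) and erythrocyte (camera adjusted p = 0.0238, and adjusted p = 0.748 with an estimated correlation) lists fell with 0 members past the threshold over all genes or adjusted over the list alone. The first was lost without P28 wild-type library 1 (0.161) and the second without 12-month wild-type library 3 or P28 wild-type library 2 (up to 0.093). Outside the called lists, the survival gene Bcl2 (log2 fold change 1.27 ± 0.09, adjusted p = 4.68e-06) and the spindle checkpoint kinase Bub1b (log2 fold change 1.78 ± 0.20, adjusted p = 0.000143) rose. Abca1 (log2 fold change 1.403 ± 0.17, adjusted p = 0.000323) and Acadm, of mitochondrial fatty acid oxidation (log2 fold change 0.92 ± 0.12, adjusted p = 0.000628), rose as well. Sparc, an extracellular matrix protein gene, fell (log2 fold change -1.56 ± 0.26, adjusted p = 0.00316). In all 891 genes passed limma, 602 up and 289 down, with 3207 at unadjusted p under 0.05. The ages did not overlap for each of these 891 genes and for 34.9% of all genes, where chance gives 10%. The count was 460, 418 and 457 without 12-month wild-type libraries 1, 2 and 3, and 512, 539 and 450 without the P28 ones. It was 361 with a sex term and 2293 when only these 6 libraries were fitted.

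To describe ageing in knockout retina, 12 months was compared with P28 in that genotype (n = 3 each, 2 female libraries at P28 and 0 at 12 months). Hdc (log2 fold change 3.90 ± 0.42, adjusted p = 7.93e-05), Glb1l3 (log2 fold change 3.33 ± 0.13, adjusted p = 2.29e-08) and Col4a3 (log2 fold change 2.99 ± 0.53, adjusted p = 0.00223) rose and Crygb fell (log2 fold change -3.79 ± 1.05, adjusted p = 0.0198). Lens transcripts summed to 51.2 to 5951 CPM at P28 and 23.4 to 848 CPM at 12 months in knockout. Further rises were in the glucocorticoid-induced kinase Sgk1 (2.63), the fatty acid receptor Cd36 (2.16), Bst1 (3.11), Kif4 (2.24), mt-Nd3 (2.18), Ly75 (2.26), Csrp3 (2.34), Fndc1 (2.33), Pate2 (2.16) and Shisal2b (2.53). Their adjusted p ran from 1.53e-06 to 0.00179. Further falls were in the microfibril gene Fbn2 (-2.02), the protocadherin Pcdhgc4 (-1.97), Tmem26 (-3.20), Ccdc187 (-2.38), Wdr63 (-2.22), Tmem254c (-1.95) and Apobec2 (-2.24, again under 2 identifiers). Adjusted p for these ran from 9.93e-06 to 0.0106. Duxbl1 (-3.68), Duxbl2 (-2.75) and Duxbl3 (-4.16), which share reads, fell too.

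In knockout 9 of the 35 lists passed with age, 5 of them in the same direction with GC and length trends removed and 0 with an estimated correlation. The interferon list rose with age in knockout too (median 0.73; camera adjusted p = 6.78e-08, and adjusted p = 0.607 with an estimated correlation), 13 of 20 over all genes and 15 adjusted over the list alone. Ifit1 was at log2 fold change 1.94 ± 0.17, adjusted p = 1.47e-05, and Gbp2 at 1.36, adjusted p = 0.000598. Endothelial and pericyte markers fell (median -0.60; camera adjusted p = 0.00254, and adjusted p = 0.607 with an estimated correlation), 8 of 15 over all genes and 10 lower and 1 higher adjusted over the list alone. VE-cadherin gene Cdh5 was at log2 fold change -0.84 ± 0.15, adjusted p = 0.00248. Extracellular matrix genes fell (median -0.88; camera adjusted p = 0.00273, and adjusted p = 0.607 with an estimated correlation), 12 of 29 lower and 3 higher over all genes and 17 and 3 adjusted over the list alone. Sparc was at -1.88, adjusted p = 0.000461, Htra1 at -1.27, adjusted p = 0.000567, and Efemp1 higher at 0.91, adjusted p = 0.00327. Calcium handling fell (camera adjusted p = 0.0212, and adjusted p = 0.607 with an estimated correlation; 8 of 24 lower and 1 higher, 9 and 1 adjusted over the list alone). It was lost without P28 knockout library 3 (0.051), and was at adjusted p = 0.0756 with GC and length trends removed. Retinal ganglion cell markers fell (camera adjusted p = 0.0368, and adjusted p = 0.668 with an estimated correlation; 6 of 17 over all genes and adjusted over the list alone). Nefh was at -0.93, adjusted p = 0.000574, and Thy1 at -0.72, adjusted p = 0.0134. Cone genes fell (camera adjusted p = 0.0391, and adjusted p = 0.607 with an estimated correlation; 5 of 15, and 6 adjusted over the list alone). Opn1mw, the medium-wavelength opsin, was at -0.71, adjusted p = 0.000892. With the trends removed 16 interferon genes rose, and 4 endothelial, 4 extracellular matrix, 3 calcium handling, 6 ganglion cell and 5 cone genes fell, beside rises of 1, 2, 1, 0 and 1 in these lists.

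Glycolysis fell (camera adjusted p = 0.0428, and adjusted p = 0.668 with an estimated correlation; 7 of 21 lower and 2 higher, 13 and 3 adjusted over the list alone). This list (adjusted p = 0.156) and the respiratory chain (0.13) did not pass with GC and length trends removed. Hk2 was higher, at 1.33, adjusted p = 7.93e-05, and Pdk1 lower, at -0.63, adjusted p = 0.000855. The respiratory chain rose (camera adjusted p = 0.043, and adjusted p = 0.668 with an estimated correlation; 13 of 32 higher and 2 lower, 14 and 5 adjusted over the list alone). The succinate dehydrogenase gene Sdha was at 0.56, adjusted p = 0.000379, and mt-Cytb at 1.06, adjusted p = 0.00197. The locus neighbours fell (camera adjusted p = 0.0329, and adjusted p = 0.668 with an estimated correlation; 9 of 34 lower and 1 higher, 10 and 1 adjusted over the list alone), at adjusted p = 0.703 with GC and length trends removed. Within 1 Mb Col26a1, Plod3, Ap1s1, Gpc2, Actl6b, Gnb2, Gm20605, Agfg2, Tsc22d4, Stag3, Zscan21, Mospd3 and Znhit1 fell and Zcwpw1 and Zfp68 rose. After trend removal 7 of the 54 rose and 5 fell. The ganglion cell call was lost without 12-month knockout library 3 or P28 knockout library 1 or 3 (up to 0.172), the cone call without 12-month knockout library 3 or P28 knockout library 2 or 3 (up to 0.0653), and the glycolysis call without 12-month knockout library 2 or P28 knockout library 1 or 2 (up to 0.137). The respiratory chain call was lost without 12-month knockout library 1 or 3 or P28 knockout library 2 (up to 0.0692) and the neighbour call without 12-month knockout library 2 or P28 knockout library 1 or 2 (up to 0.0832). In all 4483 genes passed limma, 2198 up and 2285 down, with 6809 at unadjusted p under 0.05. The larger share turned, at 2345 and 1939 after quantile normalization, 2391 and 2179 after median-of-ratios rescaling, 2434 and 2125 with recomputed TMM, 2295 and 1898 with summed transcript RPKM and 1940 and 1608 with GC and length trends removed. The ages did not overlap for 4125 of them and for 36% of all genes, where chance gives 10%. The count was 2468 without 12-month knockout library 2, 2806 without P28 knockout library 1 and 1569 when only these 6 libraries were fitted.

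To compare ageing between genotypes, the calls of both age comparisons, which share no library, were overlapped. Genes called in both numbered 421 in the up direction, against 80.3 for independent calls, and 178 in the down direction, against 40.1, with 7 in opposite directions. Glb1l3, Hdc, Col4a3, Csrp3, Ly75 and Shisal2b were among the 13 largest rises in each genotype, and Crygb, Duxbl1, Duxbl2, Duxbl3, Tmem26, Wdr63 and Apobec2 among the 12 largest falls. The age effects correlated at Pearson r = 0.376 across genes, and at 0.521 with GC and length trends removed. The genes whose age effect differed between the genotypes are the 29 above, since that difference is the same contrast.

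**Figure D4:**
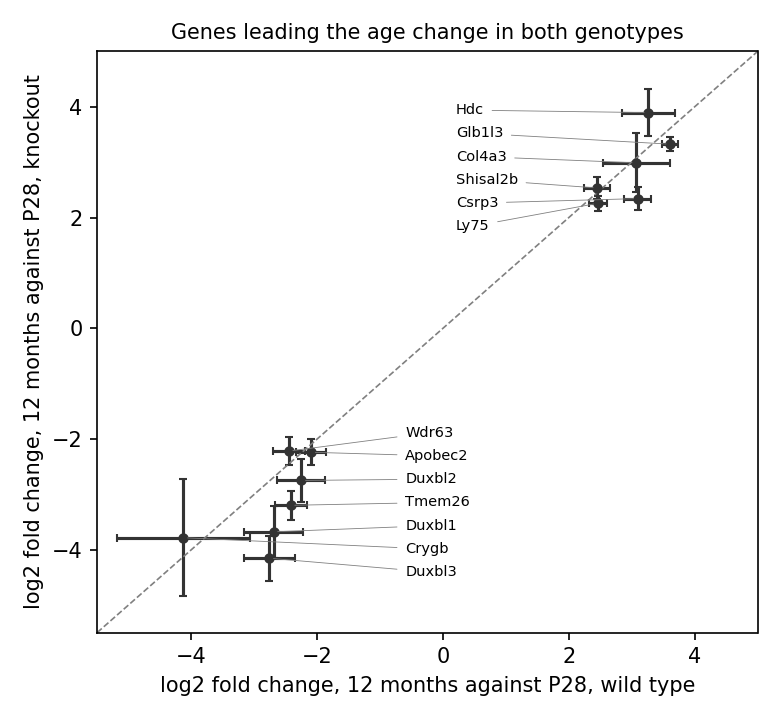
Log2 fold change with age (12 months against P28) in wild type and in knockout, with standard errors, for the 13 genes among the largest age changes of both genotypes; the dashed line marks equal change. Hdc was at 3.26 ± 0.42 in wild type and 3.90 ± 0.42 in knockout, and Duxbl3 at -2.76 ± 0.40 and -4.16 ± 0.40.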

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

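The splits of the libraries and the within-gene GC slope were planned before the results they test, and the other 8 tests below were chosen after the result was seen. The difference between the ages in the knockout effect passed its own test (limma, 12 months minus P28) in 29 genes. Cohesin regulator Pds5a (1.503 ± 0.13, adjusted p = 0.000958) went from -1.01 at P28 to 0.49 at 12 months. Positive differences were also found in Hnrnpa1 (0.78, adjusted p = 0.0244), Hnrnpdl (0.79, adjusted p = 0.041), Srsf3 (0.80, adjusted p = 0.041), Mfap1b (0.59, adjusted p = 0.0478) and Nol11 (0.66, adjusted p = 0.041). They were found as well in the mitochondrial genes mt-Nd3 (1.80, adjusted p = 0.0244) and mt-Nd2 (1.45, adjusted p = 0.0478), the chromatin protein gene Hmgb2 (1.02, adjusted p = 0.0329), the kinase gene Stk17b (0.96, adjusted p = 0.0344), the hexokinase Hk2 (1.24, adjusted p = 0.041), A930006I01Rik (0.72, adjusted p = 0.041) and D16Ertd472e (0.71, adjusted p = 0.0478). With GC and length trends removed 5 genes passed, and Pds5a, Hnrnpa1 and Hk2 were shared.

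Negative differences were found at adjusted p = 0.0372 in the kinase gene Map4k4 (-0.95) and Selenbp1 (-1.497). At 0.041 were the endocytic receptor Lrp2 (-1.09), Tnrc18 (-1.59) and Cpt1a, which carries fatty acids into mitochondria (-0.85). At 0.0478 were the microglial receptor gene Cx3cr1 (-1.05), the kinase gene Dgkd (-0.73), the transcription factor Etv5 (-0.85) and the collagen Col23a1 (-0.89). Zc3h3 (-1.38), Hap1 (-1.27), Haghl (-1.14) and Mtus2 (-0.79) were also at 0.0478. AC149090.1 (-1.81, adjusted p = 0.0244) and Gm20742 (-1.60, adjusted p = 0.0414) carry clone names. The fitted difference of Acte1 (-1.32, adjusted p = 0.0329) rests on 9 libraries listed at 0.

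Other splits of the same libraries were fitted beside the real ones, 100 drawn within age and, after these were seen, all 200 possible. Over both ages 1 of the 100, the real one, gave 5796 genes or more and the highest other 4068. Of all 200, 2 did, a share under 0.05, and the other gave 5985 with the 12-month libraries parted by genotype and the P28 ones not. The 180 splits that do not part the 12-month libraries by genotype gave at most 3 genes. The count thus rests on the 12-month parting, where the real split is 1 of 10, so this share does not exclude chance for it. The count over both ages therefore does not show an effect at P28. For the difference between ages 7 of the 100, and 11 of all 200, gave 29 genes or more, the real one included. All others that large part the 12-month libraries by genotype, so their counts hold the 12-month genotype difference and do not test chance. The highest gave 5985 genes, and the 180 splits that do not part them gave at most 3, but those leave that difference in the spread. In 1 of those that part them, at 5796 genes, the P28 libraries are parted by genotype too, with the labels exchanged at 1 age. For the correlation of the knockout effects between ages 11 of 100 splits gave r = 0.364 or higher, the real one included, with 0.468 in the highest other, and 19 of all 200 did, with 0.509 in the highest, so chance cannot be excluded for it. Splits of 3 against 3 are too few for a share under 0.05, since the real one is 1 of 10 in each comparison. The real split gave 246 genes at P28 (highest other 7), 6536 at 12 months (0), 891 with age in wild type (0) and 4483 with age in knockout (0). The other splits leave the real difference in the spread, so their low counts do not test chance.

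The 12-month knockout difference followed GC content across genes. The trend removed was a smooth one in the GC and length of the transcript with the most reads in each gene. That trend was argued against as the whole source of the calls, since 829 of 6536 calls, 12.7%, passed in the same direction without it. The effect also followed GC between transcripts of the same gene, so GC bias may remain after the removal and is not excluded as a source of the 829 calls. Sex was argued against as the source of the GC trend, as the Spearman correlation was -0.785 with a sex term and -0.773 without. A GC bias of single libraries is a candidate explanation for the trend. Transcripts of the same gene differed by -0.77 log2 per 10 points of GC against -0.56 between genes, a ratio of 1.36 (7931 genes). Its 95% interval, 1.31 to 1.42, was drawn over genes and does not measure the spread between libraries. Whether such a bias arose in the RNA or in library preparation was not tested. Sex of the animals cannot be told apart from the deletion for the 829 calls, because 2 of the 3 wild-type libraries and 0 of the 3 knockout ones are female, and the 1 male wild-type library, with effects at 0.533 to 0.894 of their size in the female ones (200 genes picked without it), excludes nothing alone. With a sex term 38 of the 829 passed, and their median standard error went from 0.135 to 0.165 while their median effect was 0.586 before and 0.588 after.

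The P28 calls rested on few libraries, the count running from 3 without P28 wild-type library 3 to 1404 without P28 knockout library 2. It was 7, 81 and 6 without wild-type libraries 1 and 2 and knockout library 3. Lens tissue in knockout library 2, the richest in it, was argued against as the source of the calls, since 1404 genes passed without that library. Sex of the animals cannot be told apart from the deletion, because 2 of the 3 knockout libraries and 0 of the 3 wild-type ones are female. Of 200 genes picked from the female knockout libraries, the median signed effect in the male knockout library was 0.361 of its size in the lowest of the 3 choices of wild-type library and 0.54 and 0.493 in the others, with 90.5 to 93.5% of genes of the same sign.

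The rod list was lower in knockout at P28 and over both ages and the cone list at 12 months and over both ages, and with an estimated correlation none of these passed (adjusted p = 0.577, 0.903, 0.689 and 0.733). With 1 library left out the rod call over both ages was kept in 5 of 12 fits and the cone call in 8 of 12. The 12-month cone call was kept in 4 of 6. Adjusted p rose to 0.0931, 0.072 and 0.0968. A GC and length trend was argued against as the whole source of the lower rod list over both ages. The list median was -0.14 before and -0.133 after its removal (camera adjusted p = 0.00186), and the mean -0.248 and -0.158. GC bias may remain after the removal. At 12 months alone the mean went from -0.266 to -0.103 and the list was at camera adjusted p = 0.426 after it. A sex effect of the same size at both ages was argued against, since the mean of the 28 rod genes over both ages, where the sexes balance, was -0.248 ± 0.068 with a sex term and -0.158 ± 0.050 with the trends removed as well (standard errors over libraries; 95% upper end at most -0.040, and -0.010 without 12-month wild-type library 1), but one that differs between the ages stays open, as the same intervals ended above 0 at P28 (-0.241 ± 0.117, up to 0.036) and at 12 months (-0.256 ± 0.117, up to 0.021), and with the trends removed at 12 months (-0.074 ± 0.087, up to 0.131) but not at P28 (-0.242 ± 0.087, up to -0.037). A lower share of photoreceptor cells cannot be told apart from lower transcript levels within them. Over both ages, with GC and length trends removed, the medians of 5 other retinal cell types lay between -0.04 and 0.05. Their intervals, drawn over the genes of each list and not over libraries, include 0 (lowest upper end 0.080) and so do not decide it. An effect of the deletion stays open and was not tested.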

How the results depend on the processing

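Alternatives that remove GC or length trends, take male libraries only or leave out both knockout libraries numbered 2 were chosen after the data were seen, and the others were planned. Counts stayed within 1.5 times the reported one in 9 of 19 alternatives other than leave-one-out at P28, 15 of 19 at 12 months and 14 of 18 over both ages. For the difference between ages it was 7 of 18, for age in wild type 12 of 18 and for age in knockout 15 of 19. Of the rest 5, 4, 4, 7, 3 and 3 were lower and 5, 0, 0, 4, 3 and 1 higher. No named gene that passed changed direction in the settings tried for named genes. The largest rises and falls were named for libraries that did not overlap, so leaving out 1 library or changing the pseudocount could not turn them. For these genes only quantile normalization and trend removal could have done so. The cause of the changes below was not tested.

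Without a filter 67 genes passed at P28 and 5 for the difference between ages, and 379 passed at P28 with a mean CPM of at least 5. Fits of only the groups compared gave 0 at P28 (2615 with unadjusted p under 0.05 in limma), 2293 for age in wild type and 1569 for age in knockout. With arrayWeights the counts were 2382 at P28, 5234 for the difference, 2884 for age in wild type and 8316 for age in knockout. Summed transcript RPKM gave 5 for the difference, and an adjusted p of 0.10 gave 1039 at P28, 1656 for the difference and 1414 for age in wild type. With a sex term 1 passed at P28, 0 for the difference (2962 with unadjusted p under 0.05 in limma) and 361 for age in wild type. A replicate block gave 1221 for the difference, but like-numbered libraries were not closest to each other throughout, so the numbers do not pair the libraries.

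Removing the GC trend gave 650 at P28, 1156 at 12 months, 2300 over both ages and 4 for the difference, and removing GC and length trends gave 1196, 1704 and 5 in the last 3. With a sex term as well the counts were 2 at P28, 61 at 12 months, 1476 over both ages, 1 for the difference, 529 for age in wild type and 1982 for age in knockout. Male libraries only gave 23, 2597, 413, 3, 240 and 2098 in the same order, with fewer libraries and 1 library in an arm at each age, assumed to vary like the others. Leaving out both knockout libraries numbered 2 gave 2278 at P28 and 148 for the difference.

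Leaving out 1 library gave 3 to 1404 genes at P28 (lowest without P28 wild-type library 3, highest without P28 knockout library 2), 3552 to 6607 at 12 months, 4303 to 7566 over both ages, 1 to 2501 for the difference (lowest without 12-month wild-type library 2, highest without P28 knockout library 3), 418 to 539 for age in wild type and 2468 to 5539 for age in knockout. The lists that passed numbered 55 over the 6 comparisons, 0 with the correlation estimated from the data, 50 to 77 in the other 4 alternatives and 44 to 68 in the leave-one-out fits. Pilra's exact p over both ages was 0.04 with summed RPKM and 0.01 to 0.135 with 1 library left out. Of 85 calls of named genes 50 to 84 passed with 1 library left out (55 without P28 wild-type library 1), and 108 of 131 with GC and length trends removed. The correlation of knockout effects was 0.136 to 0.47 with 1 library left out, and 0.179 with GC and length trends removed. Depth limits the targeted genes, since a floor of 3 reads was 0.111 to 0.192 CPM.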

Other observations

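The lists that passed in no comparison also held single genes that did. At 12 months the visual cycle gene Rdh5 (-0.997, adjusted p = 0.00371) fell, while its list did not pass (camera adjusted p = 0.0512, and adjusted p = 0.689 with an estimated correlation; 7 of 16 lower and 1 higher over all genes, 9 and 1 adjusted over the list alone). Medians at P28 and 12 months were 0.02 and -0.35 for the visual cycle, 0.06 and -0.21 for bipolar cells, 0.11 and -0.18 for horizontal cells, -0.05 and -0.10 for Mueller glia and 0.12 and -0.98 for pigment epithelium. They were 0.02 and -0.17 for the ribbon synapse, 0.09 and -0.40 for astrocytes and optic nerve and 0.12 and 0.02 for cornea, iris and ciliary body. Pathway medians were 0.03 and -0.01 for fatty acid and phospholipid metabolism, 0.00 and 0.12 for the p53 response, -0.17 and 0.09 for the cell cycle and -0.02 and -0.23 for the circadian clock. The 12-month medians with GC and length trends removed, in the same order, were -0.18, 0.00, -0.02, -0.01, -0.86, 0.06, -0.22, -0.01, -0.02, 0.08, 0.06 and 0.03, and those at P28 0.10, 0.11, 0.09, -0.03, 0.08, -0.04, 0.13, 0.12, -0.02, 0.06, -0.13 and -0.03. Rdh5 was then at -0.49 (adjusted p = 0.199) at 12 months, and 1 visual cycle gene fell and 1 rose.

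Of 5 genes that differ between C57BL/6 substrains, Nnt, a mitochondrial transhydrogenase, was at 0.07 ± 0.21, adjusted p = 0.883 at P28, and at 0.68 ± 0.21, adjusted p = 0.0212 at 12 months. Entpd4b was at -0.28 ± 0.11, adjusted p = 0.173 and -0.47 ± 0.11, adjusted p = 0.00766, and Entpd4, a near-identical copy that shares reads with it, at -0.60 ± 0.20, adjusted p = 0.0298 at 12 months. Wdfy1 and Crb1 did not pass at either age. Pearson correlations of log2 values between libraries were 0.971 to 0.994 within groups and 0.946 to 0.988 between them. The first principal component held 38.1% of the variance, and its loadings correlated with GC content at Spearman -0.76.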
